A study of Mus musculus with 12 samples.

How the data were processed

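Hearts of Balb/c mice were profiled after a single gavage of 30 mg/kg body weight of a compound labelled DMA, an abbreviation that the labels do not expand, or of its vehicle DMSO. Hearts were taken 24 h or 48 h after dosing, which gave 4 groups of 3 arrays, called biological replicates in the labels. The design text says that total RNA of each group's hearts was isolated as a pool, so the p-values below measure the spread between the 3 samples of a group, which may be partly technical. Per the labels, RNA was extracted from myocardium, polyA RNA was copied into biotinylated cRNA, and the cRNA was hybridised and stained with streptavidin-Cy5 on 1-colour arrays.

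The deposited table held log2 values for 36227 probes on 12 arrays, with no header on how they were scaled; the background correction and the normalization were not given in the sources used here. Maxima of the log2 values lay between 14.53 and 15.12. Medians lay between 6.03 and 6.04 on the 24 h arrays and between 6.35 and 6.36 on the 48 h arrays, and the 25% and 75% quantiles were equally tight within each time and different between the times. The values therefore had the form of a table scaled separately within each time. Differences between DMA and DMSO of one time were not touched by this, and any level set across the times carried it. Between 322 and 3997 probes per array had no value. Heart transcripts of very high level were among these: Actc1 and Atp2a2 had no value on any array, and Tnni3, Pln, Myl2 and Fabp3 had a value on 1 array each.

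Probes were tested if each of the 4 groups had at least 2 values, which kept 35401 and left out 826. Gene names came from the platform annotation: 21615 probes had 1 symbol, 681 had several and were not named, and 13931 had none. Of the named probes, 21487 were found by gene identifier in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. For gene-level work the probe with the highest mean of each gene was used, which gave 17679 genes.

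Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a term for each of the 4 groups, all 12 arrays), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Contrasts were DMA against DMSO at 24 h, at 48 h and over both times, the difference of the DMA effect between the times, and DMSO at 48 h against DMSO at 24 h as the background with no DMA. Before the data were examined, 35 gene lists with 986 genes were fixed (pathways and markers of cell types that a dissected heart can hold), and 790 of these genes were tested. For 74 more the named probe had too few values. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, and again with an estimated correlation. For these tests 2.81% of the gene values were missing and were filled with the mean of their group. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

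The fit was tested on simulated data. At 24 h, over 35401 probes, it recovered 2%, 20%, 54% and 74% of probes changed by 1, 2, 3 and 4 log2 units, with 4 false calls. At 48 h it recovered 0%, 12%, 52% and 80%, with 1 false call. With 3 lists shifted by 0.5 log2 at 48 h over 17679 genes, camera found 2 and called 0 others. The simulated noise was independent between probes, so this run did not test the preset correlation of 0.01. For each probe it had the same spread on all 12 arrays, with no array that stood apart, no trend along the probe numbers and no pairing. In the real data the estimated correlation was -0.0481 to 0.257 over the lists, 0.216 for endothelial markers and 0.00348 for immediate early genes. The number of arrays limits the precision, and in this simulation the single-probe test found only changes of several log2 units in most cases. The simulated spread was estimated from all 12 arrays, so any array that stands apart also enters it.

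The labels number the replicates 1 to 3 in every group, and whether these numbers pair DMA with DMSO samples was checked from the deviations from the group means. Same-numbered samples correlated at 0.105 to 0.19 at 24 h and at 0.276 to 0.335 at 48 h, and samples of different numbers at -0.0981 to -0.0118 and at -0.208 to -0.0926. Each same-number pair was above 0.1, so the numbers were taken to pair the samples within a time, a pairing that comes from the data and that the labels do not explain. Fits with the replicate number as a block were run as alternatives.

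Named genes followed a rule fixed beforehand. For DMA at each time, up to 12 genes per direction with an adjusted p under the threshold and no overlap between the groups were to be named. Where fewer than 12 passed, the list was filled to 6 per direction with non-overlapping genes of the smallest unadjusted p. Up to 4 members of the smallest p were added from each list that passed and from 4 lists that fit an oral compound and the heart (Nrf2 and glutathione, foreign compound metabolism, natriuretic and stretch response, fatty acid use). For the difference between the times and the vehicle comparison, up to 5 per direction were to be named, filled to 3. Symbols of unnamed transcripts were skipped.

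Alternatives fixed beforehand were quantile normalization over the 12 arrays, median centring, leaving out probes below the median level, probes with a value on all 12 arrays (25002), a moderated variance with an intensity trend and robust moderation, array weights, a replicate block, fits on only the 6 arrays compared, each array left out in turn, gene means over probes, and an estimated inter-gene correlation. A floor for non-positive linear values did not apply, because the deposited values were already on the log2 scale. Added after seeing the data were a block within each time, removal of a smooth trend along the probe numbers (lowess, span 0.1), genes complete on all arrays, a 6-array fit with the block, fits without the arrays in doubt, and list tests at 48 h without each pair of same-numbered arrays.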

Results

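Gene expression was measured in 12 heart samples of Balb/c mice, an inbred laboratory strain, on 1-colour arrays. The samples formed 4 groups of 3: vehicle (DMSO) at 24 h, DMA at 24 h, DMSO at 48 h and DMA at 48 h after a single oral dose. The design asked which genes of the heart respond to DMA 24 h and 48 h after gavage. Values are log2 intensities. Between 32230 and 35905 of 36227 probes had a value on an array.

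The arrays were not equally alike. DMA 24 h replicate 3 correlated at 0.742 with the median of the other 24 h arrays, and the other 11 arrays correlated at 0.927 to 0.963 with the rest of their time. On that array 503 values lay at its lowest value of 1.37, against at most 223 on any other array. It was also the array with the fewest missing values, 322, and it alone carried values for Tnni3 (13.56), Pln (13.73), Myl2 (13.44) and Fabp3 (13.73), transcripts of cardiac troponin I, phospholamban, ventricular myosin light chain and a fatty acid binding protein. On DMA 48 h replicate 3 the deviation from the other arrays ran along the probe numbers, from 0.33 log2 at the lowest numbers to -1.06 at the highest. Both arrays belong to the DMA groups, and values without them are given where they alter a result. Because the limma spread was pooled over the 4 groups, DMA 24 h replicate 3 also enters the SEs and p-values of 48 h.

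**Figure D1:**
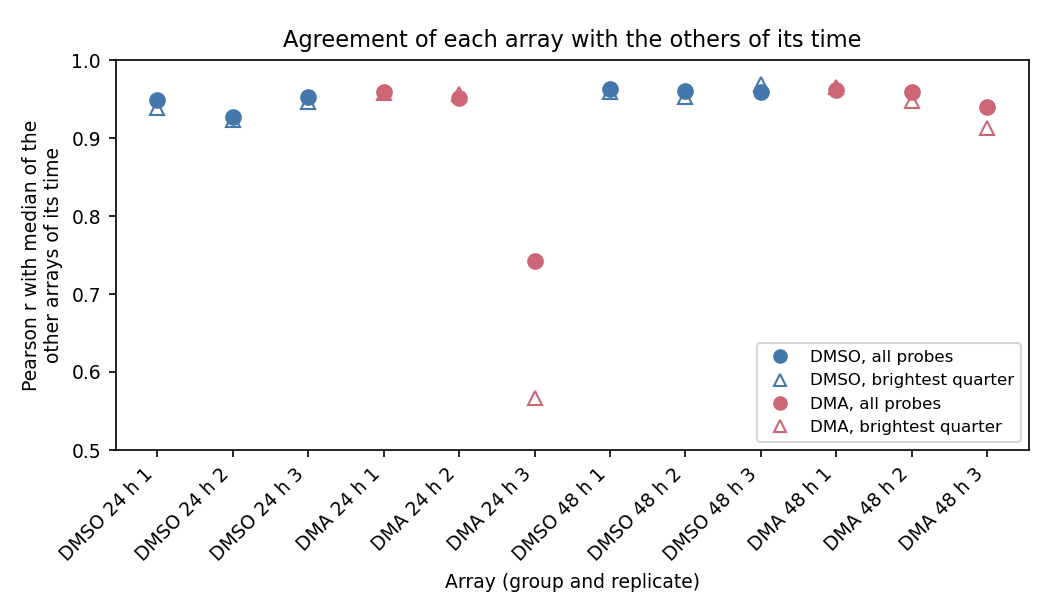
Pearson correlation across probes (y axis) of each of the 12 arrays (x axis) with the median of the other arrays of its time, over all probes (circles) and over the brightest 25% of probes (triangles); blue is DMSO and red is DMA. DMA 24 h replicate 3 lies at 0.742 and 0.566, and the other arrays lie at 0.913 or above on both measures.

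**Figure D2:**
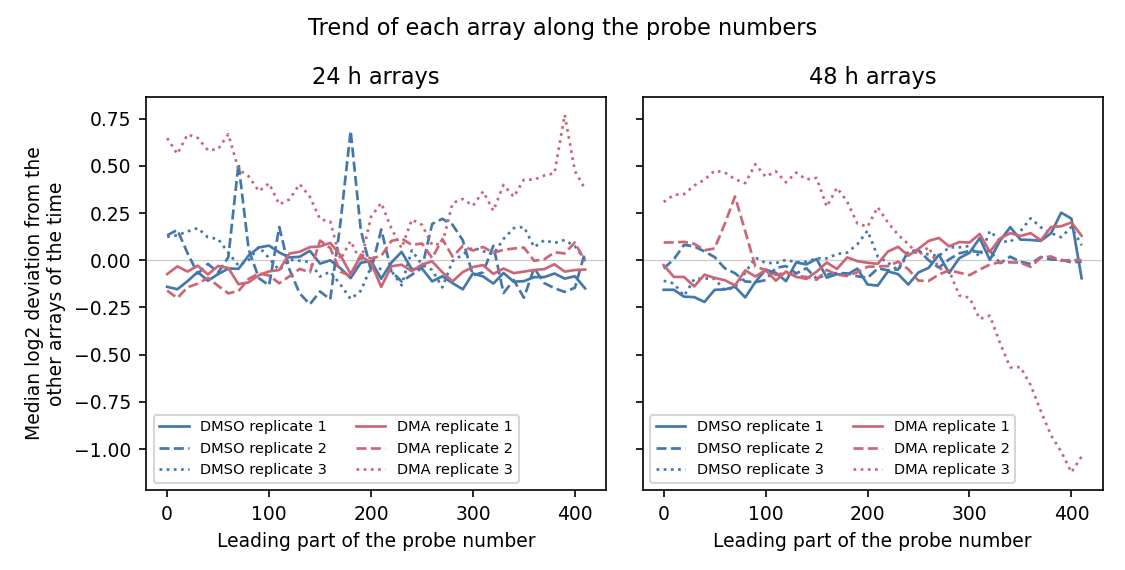
Median log2 deviation of each array from the other arrays of its time (y axis) along the leading part of the probe number (x axis), for the 24 h arrays (left) and the 48 h arrays (right); colour marks the treatment and line style the replicate. DMA 48 h replicate 3 runs from 0.33 at the lowest numbers to -1.06 at the highest, and DMA 24 h replicate 3 lies above the others at both ends, at 0.60 and 0.58.

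DMA at 24 h was compared first. No gene passed the test, and the genes with the clearest separation were mostly of low signal. Bpi, which encodes a bactericidal protein of neutrophil granules, had a mean log2 value of 4.48 ± 0.481 (SD, n = 3) after DMA and 0.939 ± 1.25 (SD, n = 3) after DMSO, a difference of 3.54 (SE 0.641, limma adjusted p = 0.871). The other 5 genes with the smallest p among those higher in each DMA array were Trem1, a receptor of myeloid cells, Icam4, Wnk4, Ddias and Slc6a8, the creatine transporter, with differences of 1.46 to 3.5. The 6 on the lower side were Vmn1r231, Tex12, an immunoglobulin kappa variable gene, Tafa1, Rtl3 and Zfp42, with differences of -4.02 to -2.07. All 12 had an adjusted p of 0.871, and 10 of the 12 had a mean level below the overall median of 6.19. For 6 of them (Bpi, Icam4, Vmn1r231, Tafa1, Rtl3 and Zfp42) at least 1 value was the lowest value of its array, so the size of their differences depends on that floor.

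Genes of foreign compound metabolism and of the Nrf2 response, which a foreign compound can induce in many tissues, did not pass at 24 h. Of 35 measured genes of foreign compound metabolism 23 had a positive and 12 a negative difference, with a median of 0.30 (camera adjusted p = 0.551). Ephx2, the soluble epoxide hydrolase, differed by 1.86 (SE 0.464) and was higher on the 3 DMA arrays than on the 2 DMSO arrays with a value, Cyp2d22 by 1.77 (SE 0.695), Cyp2j5 by 1.03 (SE 0.517) and Aldh1a1 by -2.47 (SE 1.33). The 32 Nrf2 and glutathione genes were evenly divided, with 16 positive and 16 negative and a median of 0.01 (adjusted p = 0.955). Among them Ftl1 differed by 1.37 (SE 0.632), Nqo1 by 1.43 (SE 0.725), Gsta4 by -2.05 (SE 0.96) and Prdx1, a peroxiredoxin, by -2.67 (SE 1.19). Prdx1 had values on only 2 DMA arrays, 12.98 on replicate 2 and 7.55 on replicate 3. Gsta4 and Aldh1a1 were also low on replicate 3, at 7.18 and 4.87. Without that array Gsta4 differed by -0.55, Aldh1a1 by -0.32, Nqo1 by 0.89 and Cyp2j5 by 0.585, and the Nrf2 and glutathione list passed on the higher side (median 0.33, adjusted p = 0.0234), though not with an estimated correlation. Without DMSO replicate 2 Ftl1 differed by 0.85, Nqo1 by 0.68 and Cyp2d22 by 0.94.

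Fatty acid use was the list closest to the threshold at 24 h. Its list mean was higher on the DMA array in each of the 3 same-numbered pairs, by 0.09, 0.903 and 0.255. Of its 34 measured genes 25 had a positive difference, with a median of 0.46 (adjusted p = 0.299, and 0.979 with an estimated correlation). The median of fatty acid use was 0.88 without DMSO replicate 1 (adjusted p = 0.00594) and 0.20 without DMSO replicate 2 (adjusted p = 0.796). Angptl4, an inhibitor of lipoprotein lipase, differed by 2.27 (SE 0.881), Ppara, a nuclear receptor of fatty acid oxidation, by 1.37 (SE 0.72), Hadhb, a subunit of the mitochondrial trifunctional protein, by 1.06 (SE 0.445) and the lipid droplet gene Plin5 by 0.71 (SE 0.355). Natriuretic and stretch genes had a median of 0.03 over 14 genes, 7 positive and 7 negative (adjusted p = 0.955). In that list Des, encoding desmin, differed by 1.57 (SE 0.778), Enah by -1.07 (SE 0.605), Timp1 by -1.85 (SE 1.08) and Ankrd1 by -2.28 (SE 1.64). Ankrd1 read 3.55 on DMA replicate 3 and 10.78 to 11.54 on the other DMA arrays, and its difference was 0.26 without replicate 3. Without it Enah differed by -0.20, Timp1 by -0.70, Ppara by 0.82 and Plin5 by 0.44, and without DMSO replicate 2 Des differed by 0.81. Of the 16 genes named from the lists at 24 h, 13 changed by more than 1.5 times when 1 array was left out.

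Over all 35401 probes 0 passed at 24 h in limma, with 1071 (3.03%) at an unadjusted p under 0.05 (501 in the fit on the 6 arrays of 24 h, 2146 with array weights, and 763 to 3027 over the arrays left out), and 0 list members passed over all genes or adjusted over the list alone. The count of passing probes was 9 without DMA replicate 1 and 14 without DMA replicate 2, each time with lower values only. Every one of these calls rested on DMA replicate 3 alone, the only DMA array left with a value for the probe. None of the 35 lists passed with all arrays. Besides fatty acid use, 3 pairs of the same sign were seen for lymphocyte markers and for lung and airway markers. The pair differences were 0.081, 0.575 and 0.421 (camera adjusted p = 0.551) for the former and -0.247, -0.527 and -0.018 (camera adjusted p = 0.747) for the latter. Without DMA 24 h replicate 3, 9 lists passed, each on the higher side: endothelial markers (median 0.66, adjusted p = 0.00209), fatty acid use (0.55, adjusted p = 0.00443), interferon response (0.58, adjusted p = 0.00443), Nrf2 and glutathione, antioxidant enzymes and metallothioneins, glucose use, oxidative phosphorylation, heat shock and unfolded protein response, and muscle protein breakdown. With an estimated correlation as well, 0 of these passed. Without DMSO replicate 1, fatty acid use alone passed.

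**Figure D3:**
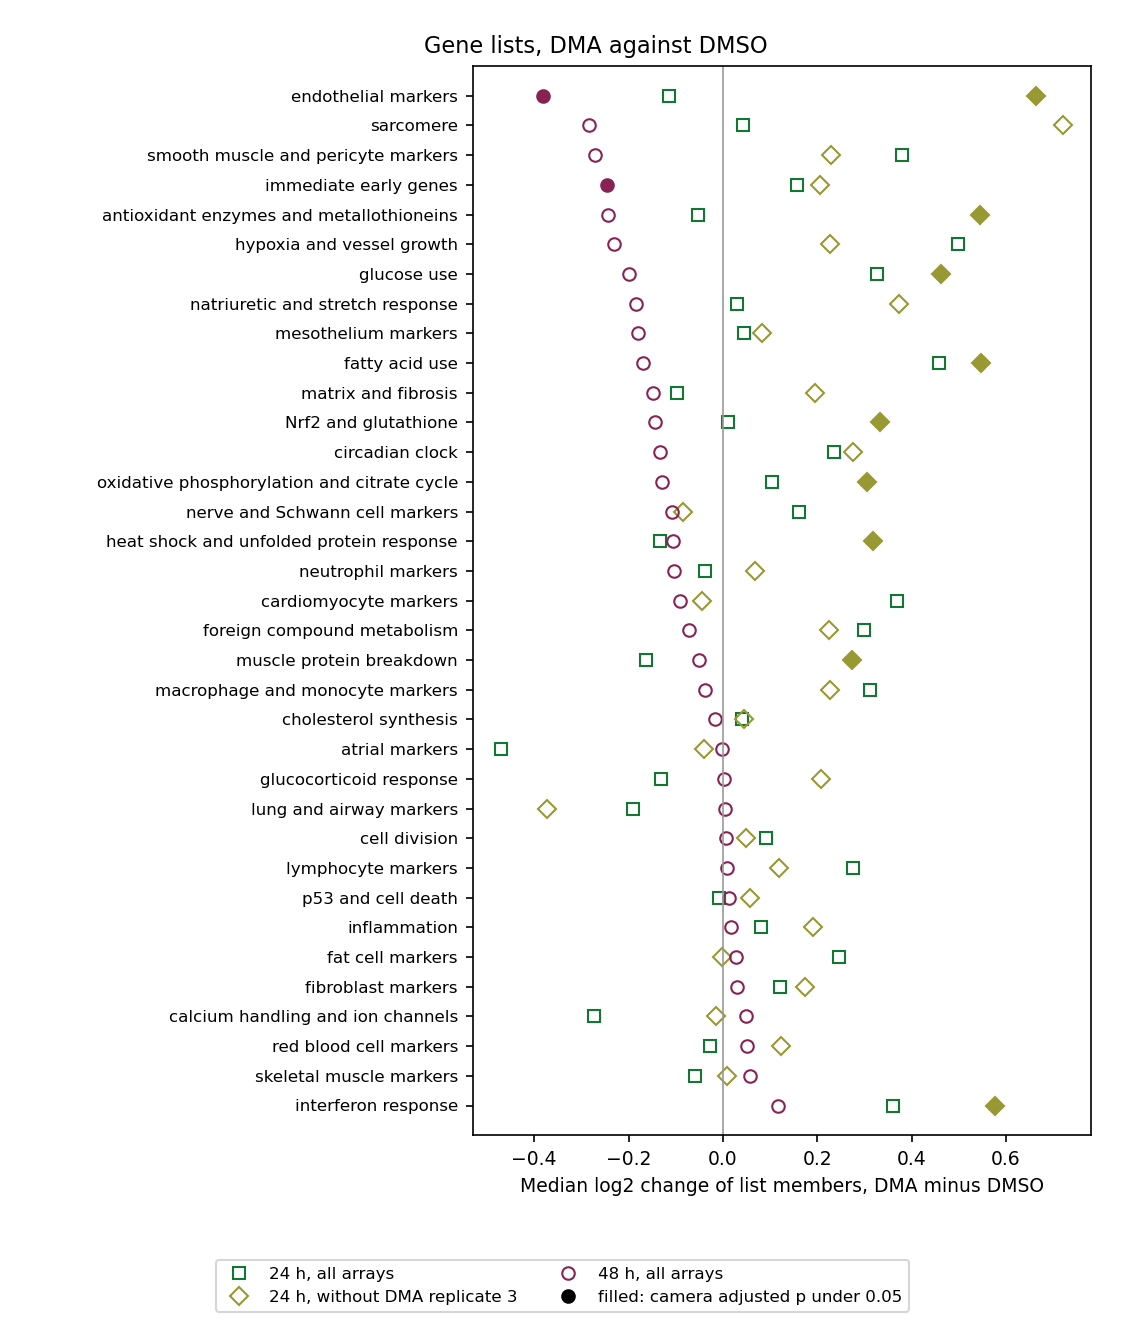
Median log2 change of the measured members of each of the 35 gene lists (y axis), DMA minus DMSO (x axis), at 24 h with all arrays (squares), at 24 h without DMA replicate 3 (diamonds) and at 48 h (circles); filled symbols have a camera adjusted p under 0.05. With all arrays no list is filled at 24 h and 2 are filled at 48 h, both on the lower side; 9 diamonds are filled, all on the higher side.

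At 48 h the DMA hearts had lower signal for endothelial markers and immediate early genes as groups, and no single gene passed. All 18 measured endothelial markers had a negative difference, with a median of -0.38 (camera adjusted p = 0.02, and adjusted p = 0.977 with an estimated correlation). Flt1 and Kdr, receptors of vascular endothelial growth factor, differed by -1.64 (SE 1.29) and -0.58 (SE 0.558), the transcription factor gene Erg by -0.75 (SE 0.667) and Cdh5, encoding the endothelial cadherin, by -0.53 (SE 0.557). Of 27 measured immediate early genes, which cells switch on within minutes of a stimulus, 20 had a negative difference, with a median of -0.24 (adjusted p = 0.0253, and adjusted p = 0.316 with an estimated correlation). Nr4a1 differed by -1.05 (SE 0.493), Junb by -0.95 (SE 0.479), Dusp1 by -0.55 (SE 0.456) and Ier2 by -0.51 (SE 0.463). Without DMSO replicate 2 Nr4a1 differed by -0.51, without DMA replicate 1 Junb by -0.61, without DMSO replicate 1 Ier2 by -0.26 and without DMA replicate 2 Cdh5 by -0.13. In both lists 0 members passed over all genes and 0 adjusted over the list alone.

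Averaged over its members, the endothelial list lay at -0.441 ± 0.484 (SD, n = 3) on the DMA arrays relative to the DMSO mean, with the DMSO arrays spread by 0.188 (SD, n = 3). The exact permutation test over the 6 arrays gave a two-sided p of 0.2, where 3 against 3 cannot go below 0.1. It took no account of the same-number pairs, so its p-values do not test the pair differences. The DMA array lay below its same-numbered DMSO array in each of the 3 pairs, by differences of -0.237, -0.3 and -0.785. For immediate early genes the DMA arrays lay at -0.261 ± 0.183 (SD, n = 3) with a DMSO spread of 0.121 (SD, n = 3), an exact p of 0.1, the smallest possible, and pair differences of -0.172, -0.261 and -0.35. Among all 35 lists at either time, only lymphocyte markers at 24 h also reached an exact p of 0.1. Immediate early genes had been chosen for their shift on these arrays, so this p is not independent of that choice.

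**Figure D4:**
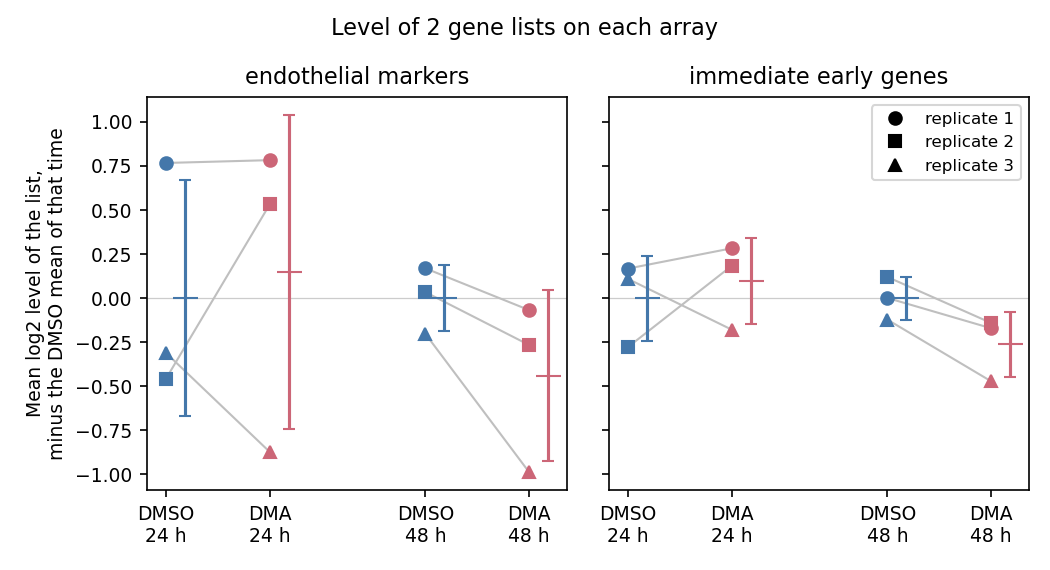
Mean log2 level of endothelial markers (left) and immediate early genes (right) on each array, minus the DMSO mean of that time (y axis), by group (x axis); symbols mark the replicate number, grey lines join same-numbered arrays, and bars are the mean ± SD of 3 arrays. At 48 h each DMA array lies below its same-numbered DMSO array in both lists, and DMA replicate 3 lies lowest.

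Both calls were lost on leaving out any of 3 arrays. Without DMA 48 h replicate 3, the array with the trend along the probe numbers, the endothelial median was -0.10 (adjusted p = 0.823) and the immediate early median was -0.07 (adjusted p = 0.597), and 0 of 35 lists passed. With its same-numbered DMSO array left out as well, the medians were -0.18 (adjusted p = 0.643) and -0.18 (adjusted p = 0.39). No list passed without DMSO 48 h replicate 1 or without DMSO 48 h replicate 2 either, where the endothelial medians were -0.37 (adjusted p = 0.0763) and -0.30 (adjusted p = 0.148) and the immediate early medians -0.15 (adjusted p = 0.0763) and -0.17 (adjusted p = 0.214). Without DMA replicate 1 only endothelial markers passed (-0.58, adjusted p = 0.0192). Without DMA replicate 2 the count was 5, with mesothelium markers (-0.38, adjusted p = 0.00471), Nrf2 and glutathione (-0.32, adjusted p = 0.00471) and macrophage and monocyte markers (-0.37, adjusted p = 0.0223) added on the lower side. With probes below the median level left out, oxidative phosphorylation (-0.17, adjusted p = 0.0152) and mesothelium markers (-0.19, adjusted p = 0.0453) were added.

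Markers of other cell types did not pass at 48 h with all arrays and probes. Medians were -0.27 for smooth muscle and pericyte markers (adjusted p = 0.404), -0.09 for the 8 measured cardiomyocyte markers (adjusted p = 0.972), -0.04 for macrophage and monocyte markers (adjusted p = 0.956) and 0.03 for fibroblast markers (adjusted p = 0.972). For the latter the mean was -0.0034, of the opposite sign to the median. Lists of heart muscle genes were tested only in part. These were 8 of 18 cardiomyocyte markers, 14 of 24 natriuretic and stretch genes, 15 of 25 sarcomere genes and 38 of 76 of oxidative phosphorylation. Heart transcripts such as Tnnt2, Tnni3, Myl2 and Atp2a2 had too few values to be tested, so no result here covers them. Of the lists chosen for the compound and the organ, Nrf2 and glutathione had 24 of 32 genes with a negative difference (median -0.14, adjusted p = 0.358), led by Gsr, glutathione reductase, at -0.92 (SE 0.46), with Abcc1 at -0.99 (SE 0.982), Txn1 at -0.36 (SE 0.388) and Gpx2 at 0.68 (SE 0.472). Foreign compound metabolism had a median of -0.07 (adjusted p = 0.972). In it the cytochrome P450 genes Cyp2b9, Cyp2j5, Cyp1a1 and Cyp2b13 differed by 1.61 (SE 0.649), 0.88 (SE 0.517), 0.65 (SE 0.41) and -0.76 (SE 0.502). Natriuretic and stretch genes had a median of -0.18 (adjusted p = 0.625), with Nppc, encoding the C-type natriuretic peptide, at -1.41 (SE 1.06), Rcan1 at -0.64 (SE 0.54), Des at -0.41 (SE 0.778) and Hbegf at -0.17 (SE 0.338). Fatty acid use had a median of -0.17 (adjusted p = 0.956), with Lipe at 0.69 (SE 0.502), Slc25a20 at -1.27 (SE 1.13), Hadhb at -0.48 (SE 0.497) and Acaa2 at -0.70 (SE 0.944). Without DMA 48 h replicate 3 the differences of Nppc, Des, Slc25a20 and Acaa2 were positive, at 0.09, 0.36, 0.28 and 0.36, and those of Abcc1, Txn1, Rcan1, Erg and Kdr were -0.27, -0.06, -0.10, -0.14 and -0.26, with Hadhb at -0.22. Gsr differed by -0.46 and Cyp2b13 by -0.23 without DMSO replicate 1, Gpx2 by 0.32 without DMSO replicate 2, Cyp2b9 by 0.81 without DMSO replicate 3 and Hbegf by -0.05 without DMA replicate 2. Of the 24 genes named from the lists at 48 h, 20 changed by more than 1.5 times when 1 array was left out.

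Genes with the clearest separation at 48 h all had a mean level below the overall median. On the higher side these were Lrrc74a, at 3.76 (SE 0.778), Ceacam13, Vmn2r37, Umodl1, Lypd10 and Krt33b, and on the lower side Vmn1r235, Spin2c, Apaf1, which encodes the scaffold of the apoptosome, Blk, Tmem40 and Taf8. Apaf1 had a mean of 4.84 ± 0.208 (SD, n = 3) after DMA and 5.92 ± 0.205 (SD, n = 3) after DMSO. All 12 had an adjusted p of 1. For Lrrc74a and Spin2c 1 value was the lowest of its array. Over 35401 probes limma called 0, with 494 (1.4%) at an unadjusted p under 0.05. In the fit on the 6 arrays of 48 h the unadjusted count was 778, and 1473 with the replicate block as well, with 0 calls in each. The count was 1 without DMA replicate 1, a probe with no gene name, and 1 without DMSO replicate 2, the gene Wdr7, with a value on only 1 of the remaining DMSO arrays. These probes were identified only from this result.

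Over both times together limma called 0 probes as changed by DMA, with 617 at an unadjusted p under 0.05. The count was 5 without DMA 24 h replicate 1 and 2 without DMA 24 h replicate 2, all on the lower side, 1 without DMA 48 h replicate 1 and 1 without DMSO 48 h replicate 2. The first 5 were Calcoco1, Rab20, D5Ertd579e and a pair of unnamed probes, the next 2 were Dcaf5 and Pcbp1, and the last 2 were the probes that passed at 48 h without the same arrays. The first 5 and the next 2 again had DMA 24 h replicate 3 as the only DMA value at 24 h. None of the 35 lists passed for the mean of the times with all arrays (smallest adjusted p = 0.692), and interferon response passed without DMA 24 h replicate 3 (0.28, adjusted p = 0.0226).

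The DMA effects at the 2 times showed little correlation across genes. Pearson's r between the log2 differences at 24 h and 48 h was -0.01 and Spearman's rho -0.01 over 17679 genes, which are not independent replicates; the 2 comparisons share no control array. The correlation was -0.11 without DMA 24 h replicate 3, 0.10 without DMA 48 h replicate 3 and 0.04 without both. The test of the difference between the times called 0 probes, with 695 at an unadjusted p under 0.05, and 0 of 35 lists, with endothelial markers and fatty acid use closest at an adjusted p of 0.134. The largest differences of low p were those of Vmn1r231 (4.86, SE 1.16), Tex12 (4.87, SE 1.22) and Lrrc74a (4.31, SE 1.1) on the positive side and of Nudt12 (-2.53, SE 0.735), Slc6a8 (-2.13, SE 0.659) and Zfp874a (-1.69, SE 0.5) on the negative side, all with an adjusted p of 0.999. The count was 4 without DMA 24 h replicate 1 (Calcoco1, D5Ertd579e and a pair of unnamed probes) and 1 without DMA 24 h replicate 2 (Dcaf5), all with DMA 24 h replicate 3 as the only DMA value at 24 h. Without DMA 24 h replicate 3, 13 lists passed on the lower side, led by endothelial markers (median -1.09, adjusted p = 1.8e-05), and 0 with an estimated correlation.

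Vehicle hearts gave the background. Between DMSO at 48 h and DMSO at 24 h, which were scaled separately, the median of all genes differed by 0.41 log2, and the medians below include that shift. Cell division genes stood above it, with a median of 1.02 over 40 genes of which 39 were positive (camera adjusted p = 4.78e-05, and 0.265 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, led them with a difference of 2.24 (SE 0.39, adjusted p = 0.669 over all probes), and 2 genes of the list passed adjusted over the list alone. Glucose use (median 1.38), matrix and fibrosis (0.78), immediate early genes (0.79), hypoxia and vessel growth (0.90), endothelial markers (1.09) and oxidative phosphorylation (0.72) also passed on the higher side. Interferon response (0.34) and lung and airway markers (0.02) passed on the lower side, relative to other genes, although their medians were above 0. That made 9 lists, against 2 for DMA at 48 h, and 0 with an estimated correlation. Endothelial markers and immediate early genes, the lists lower after DMA at 48 h, were thus also lists that differed between vehicle groups. Both comparisons use the same DMSO 48 h arrays, with opposite sign, so the 2 results are not independent. After quantile normalization over the 12 arrays the median of all genes differed by 0.01. In that scaling the list medians, with the median of all genes not subtracted, were 0.56 for cell division, 0.89 for glucose use, 0.55 for endothelial markers, 0.54 for immediate early genes, 0.44 for oxidative phosphorylation, 0.37 for hypoxia and vessel growth, 0.34 for matrix and fibrosis and -0.21 for interferon response. These 8 lists passed again. Lung and airway markers (-0.38, adjusted p = 0.0584) no longer did, and 11 lists passed in all. With median centring 13 passed, lung and airway markers among them (-0.30, adjusted p = 0.037) and interferon response not (adjusted p = 0.0504). Nrf2 and glutathione, antioxidant enzymes and muscle protein breakdown passed on the higher side under both scalings and not as deposited. No probe passed in this comparison with all arrays. The number at an unadjusted p under 0.05 was 2575, and 926 with quantile normalization, 1498 with median centring, 5260 in the fit on the 6 arrays, 6641 with array weights and 1323 to 3217 over the arrays left out. Gcdh and Yipf4 were next to Cdc20 on the higher side, at 2.11 (SE 0.424) and 2.44 (SE 0.492), and Tex12, Lrrc74a and Alb, encoding albumin, led the lower side at -4.71, -3.77 and -4.10, where Lrrc74a and Alb each had 1 value at the lowest of its array. The count of passing probes was 1 without DMSO 24 h replicate 3 (Rgn, with 1 DMSO value at 24 h) and 1 without DMSO 48 h replicate 1 (an unnamed probe).

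Few probes separated the groups completely. Among 29434 probes with a value on all 6 arrays of 24 h, 5.97% had no overlap between DMA and DMSO, and among 30095 probes of 48 h 6.1%, where 10% are expected for 3 against 3 exchangeable arrays. Same-numbered arrays deviated together, which lowers that share with no effect of DMA. In the vehicle comparison the share was 26.2% of 27222 probes, with the shift between the separately scaled times included.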

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

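Of the tests in this part, the matched random lists, the removal of vehicle arrays and the splits of the list results were set out beforehand. Chosen only after the result was seen were the tests on the array that stood apart, the trend removal and the splits of the probe counts. The test without pair 3 of 48 h was also chosen then. Leaving out DMA 48 h replicate 3 was an alternative fixed beforehand, but its use to weigh that array as a cause was chosen afterwards. Groups of 3 arrays were not tested for outliers, and no probe and no list passed the test of a difference between the times with all arrays.

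DMA 24 h replicate 3 stood apart from the other arrays at r = 0.742. Removing a smooth trend along the probe numbers left r at 0.744, which argues against such a trend as the whole cause. The median of 17 measured cardiomyocyte markers on this array lay at the 89.2 percentile of its values, which argues against RNA of a tissue other than heart. A weak signal that loses only dim probes would spare bright ones, yet over the brightest 25% of probes r was 0.566 against at least 0.924 on the other 24 h arrays, and 8.99% of the brightest 10% of probes fell below that array's median, against at most 0.128% elsewhere. A different scanner setting, RNA quality and a biological difference of this sample stay open and were not tested.

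Endothelial markers and immediate early genes were lower at 48 h after DMA. Removing the trend along the probe numbers moved the medians from -0.382 to -0.289 and from -0.245 to -0.257 and left camera adjusted p values of 0.0106 and 0.0151, which argues against that trend as the whole cause, though part of the endothelial shift went with it. Of 10000 random lists matched on mean level, 0% and 0.13% had a median as low. The middle medians of the random lists were 0.00539 and 0.00862, which argues against a shift tied to signal level. Because both lists were chosen for passing against other genes, the small percentages are no further evidence of a shift. Without DMA 48 h replicate 3 the medians were -0.0983 and -0.0689, and with its same-numbered DMSO array also left out -0.181 and -0.183. By the median, the larger part of the endothelial shift thus went with that 1 DMA array, and a property of it other than the smooth trend may account for this. By list means, pairs 1 and 2 still differed by -0.237 and -0.3, against -0.441 over all 3 pairs. How much of the endothelial shift went with that array therefore depends on the measure. For immediate early genes how much went with that array is undecided. Without that array 0 of 35 lists passed at 48 h. A fit with 1 DMA array fewer has less precision and cannot exclude an effect of DMA, which stays open. Each of the 3 pairs was lower, but the lists had been chosen for their low values on these same arrays. All 3 pairs were also lower for lists that did not pass, such as hypoxia and vessel growth (-0.227, -0.254 and -0.312). Neither list passed with an estimated correlation. For endothelial markers the estimate was 0.216. For immediate early genes it was 0.00348, below the preset 0.01, and the unadjusted camera p still rose from 0.00144 to 0.00903. A higher correlation of the members thus did not end that second call.

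Without DMA 24 h replicate 3, 9 lists were higher after DMA at 24 h. All 9 of the 9 medians were reached by at most 0.31% of 10000 matched random lists. The random lists had middle medians of -0.0118 to 0.0311, which argues against a shift tied to signal level. The 9 lists had been chosen because they passed against other genes, and random genes were drawn independently. The small percentages are therefore no further evidence of a shift. Leaving out each DMSO array in turn as well left 8 of the 9 passing without replicate 1, 0 without replicate 2 and 1 without replicate 3, with a middle median of 0.533, 0.256 and 0.351. With 0 as the lowest number, the shift may come from the vehicle arrays, DMSO 24 h replicate 2 or replicate 3. The 9 medians were 0.273 to 0.663 before this step. They were 0.206 to 0.508 without DMSO replicate 2 and 0.127 to 0.798 without DMSO replicate 3. Fewer arrays also lower the precision, so the lost calls alone do not show that the shift was gone. Replicate 2 correlated with the other arrays of its time at 0.927, the lowest after DMA replicate 3. In pair 1 of same-numbered arrays the means of these lists differed by -0.179 to 0.09, apart from interferon response at 0.451. In pair 2 they differed by 0.472 to 1.07. An effect of DMA was not tested apart from the vehicle arrays and stays open.

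Other groupings of the samples were run for the counts. With 3 against 3 only 10 splits exist, too few for a share under 0.05. A real count of 0 is matched by every split, so such a comparison says nothing about chance. For probes changed at 24 h the real count was 0, 10 of the 10 splits gave as many and the highest other gave 2; at 48 h these were 0, 10 and 2, and between vehicle groups 0, 10 and 0. Over both times, and for the difference between the times, 100 of 100 drawn splits gave as many as the real 0 by construction, with a highest other of 4 in each. For lists, the real count at 24 h was 0 and the highest other 10, with 10 of the 10 splits as large; at 48 h the real count was 2 and the highest other 8, with 7 of the 10 as large. The splits with more lists at 48 h parted 1 of the 3 same-numbered pairs and kept the others together, which points to a structure by number at that time. The list counts at 24 h did not show it. There a split that parted 1 pair gave 10 lists, and splits that parted all 3 pairs gave 8 and 2. Among the 4 splits that part all 3 pairs, 2 gave at least 2 lists at 48 h and the others gave 0.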

How the results depend on the processing

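Alternatives named in the methods as added were chosen after the data were seen. The 5 probe counts stayed at 0 under each alternative other than leaving out an array, and over the arrays left out they ranged from 0 to 14 at 24 h, 0 to 1 at 48 h, 0 to 5 over both times, 0 to 4 for the difference between the times and 0 to 1 between vehicle groups. With the replicate block (paired) the probe counts were 0 and the list counts 0 at 24 h and 2 at 48 h, so it changed no call, nor did the block within each time. Lists at 24 h ranged from 0 to 9 over the arrays left out, and were 9 without both arrays in doubt. Lists at 48 h ranged from 0 to 5, and were 0 with an estimated correlation, 1 with the probes of a gene averaged (endothelial markers, with immediate early genes at an adjusted p of 0.0544), 4 without probes below the median level, 1 with genes complete on all arrays (immediate early genes, with endothelial markers at a median of -0.371, adjusted p = 0.381) 0 without both arrays in doubt, and 1, 3 and 0 with pair 1, 2 or 3 of 48 h left out; the cause was not tested. The correlation of the DMA effects ranged from -0.113 to 0.0981 over the arrays left out. Sign changes among named genes were those of Cyp2b13 at 48 h with probes averaged (0.13) and, over the arrays left out, of Prdx1 (-5.39 to 0.0424) and Ankrd1 (-3.73 to 0.258) at 24 h and of Lipe (-0.00774 to 1.40), Nppc (-2.21 to 0.0857), Des (-0.833 to 0.363), Slc25a20 (-2.11 to 0.281) and Acaa2 (-1.30 to 0.355) at 48 h. The positive ends came without DMA replicate 3 of that time, except for Lipe, which was negative without DMSO replicate 2. Both ends of Prdx1 and of Lipe rest on 1 remaining array in an arm, assumed to vary like the other groups, as do the probe calls at 24 h. No other gene named by the rule passed the threshold in an alternative run; Prdx1 did at its low end (adjusted p = 0.0328). Signal over background was not given in the sources used here, so its limit on dim probes is unknown.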

Other observations

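Over probes with a value on all 24 h arrays, 8 of 14 lists of cell type markers lay at a lower median percentile on DMA 24 h replicate 3 than on any of the others, 5 lay within their range and 1 above it. Markers of skeletal muscle lay at a median percentile of 28.2 on that array and at 38.6 to 48.4 on the others, smooth muscle and pericyte markers at 56.1 against 84.5 to 88.6, atrial markers at 63.3 against 83 to 85.8, endothelial markers at 57.7 against 67.4 to 87.7 and fibroblast markers at 71.4 against 79.1 to 84.9, and those of macrophages, nerve and lung were also below. The 8 cardiomyocyte markers measured on all of them lay at 73.8 against 66.4 to 72.4, and fat cell markers at 60 against 54.5 to 61.1. Of its values, 53 belonged to probes measured on no other array, and these lay at a median percentile of 97.6.

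At 48 h after DMA 23 of 35 list medians were below 0 and 12 above, and at 24 h 22 were above 0 and 13 below. The median of all genes was itself 0.00998 at 48 h and 0.0858 at 24 h, and some of the list medians above 0 at 24 h lay below it. Matrix and fibrosis genes had 27 of 39 members with a negative difference at 48 h (median -0.15, camera adjusted p = 0.358), oxidative phosphorylation 28 of 38 (median -0.13, adjusted p = 0.404), sarcomere genes 12 of 15 (median -0.28, adjusted p = 0.625) and hypoxia and vessel growth 16 of 22 (median -0.23, adjusted p = 0.404). For the first 3 lists the pairs did not agree, with differences of list means in pairs 1, 2 and 3 of -0.091, 0.146 and -0.528 for matrix, -0.138, 0.064 and -0.366 for oxidative phosphorylation and -0.234, 0.061 and -0.492 for sarcomere genes; those of hypoxia and vessel growth were -0.227, -0.254 and -0.312. Antioxidant enzymes and metallothioneins had 11 of 16 members with a negative difference at 48 h (median -0.24, adjusted p = 0.404). The pair differences of that list were -0.104, -0.055 and -0.647. The remaining pathway lists of inflammation (0.02), cell division (0.01), heat shock and unfolded protein response (-0.11), p53 and cell death (0.01), circadian clock (-0.13), cholesterol synthesis (-0.02), glucocorticoid response (0.00), glucose use (-0.20), muscle protein breakdown (-0.05), calcium handling (0.05) and interferon response (0.12) had an adjusted p of 0.811 or more at 48 h.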
